A study of Homo sapiens with 24 samples.

How the data were processed

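Genomic DNA of 24 libraries was studied, 3 at each of 8 stages from CD34-positive cord blood cells to orthochromatic erythroblasts. Per the series description, enhanced reduced representation bisulfite sequencing gave single-end reads of 51 bases on an Illumina HiSeq. Per the submitters' processing notes, the tools named were Trim Galore 0.4.0, Bismark 0.14.3 and methylKit 1.2.4, and the genome build was hg19; their settings are not given in the sources used here. Per the file headers, each deposited file lists cytosines with a position, a strand, a coverage count and the percent of reads that kept or lost the cytosine. The lowest coverage count in the deposited files was 10 in each library, so cytosines read fewer times were outside the listing. The percent values in the deposited files summed to 100 within 0.01 at each cytosine. Methylated reads were recovered as coverage times percent, and these whole counts gave back the percent values within 0.005 points.

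Both strands of a CpG were summed. CpGs were used on the 22 autosomes only. A CpG entered when its summed coverage was at least 10 in all 24 libraries, which left 1909139 CpGs, or 59.1% of the 3232412 covered in any library. Requiring coverage in every library keeps the same CpGs in each comparison, and it leaves out CpGs that a shallow library did not reach. They were grouped into tiles of 1000 bases, and 159381 tiles with at least 3 such CpGs were tested, holding 1768817 CpGs. Sex chromosomes were left out. The series gives no bisulfite conversion rate in the sources used here. Bases that failed to convert raise all levels, and reads without molecular identifiers are not independent molecules, so read numbers overstate the precision of a value. The spread between libraries, and not the read number alone, set the error in each test.

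The overall level of a library was the mean percent over common CpGs, each CpG with equal weight. A two-sided exact permutation test compared HSPC with Ortho, and random shuffles of the libraries tested the trend over stages with Pearson's r and Spearman's rho. Tiles were tested with a quasi-binomial model on methylated and total reads. Its dispersion came from all 24 libraries, was moderated over tiles with limma and was kept at 1 or above. Replicates differed more in LBaso, Poly and Ortho than in progenitors, so this shared dispersion can understate the error of late steps. The median dispersion before moderation was 3.40, with 16 residual and 4.25 prior degrees of freedom. A tile was called when its Benjamini-Hochberg adjusted p was under 0.05 and its stage means differed by at least 10 percentage points, in the direction of the pooled reads. Differences are the later stage minus the earlier. Neighbouring stages, HSPC against CFUE, ProE against Ortho and HSPC against Ortho were compared, and 1 test covered all 8 stages. Named tiles were chosen by a rule: the 5 called tiles with the largest gain and the 5 with the largest loss for HSPC to Ortho, HSPC to CFUE and ProE to Ortho, and 3 of each for the other comparisons, where all 3 libraries of one stage lay above all 3 of the other. These tests, alternatives and rules were fixed before the data were examined, except where a sentence says otherwise. The planned trend test was Spearman's rho over all 24 libraries, and Pearson's r and the trends over fewer libraries were added to it. Tests on promoters and gene lists had been planned as well. They were not run, because the gene table at hand was on GRCh38 and the files on hg19. No gene is named for the same reason, and positions are given as hg19 coordinates.

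On simulated data with the real read numbers, 100 tiles of ProE to Ortho changed by 15 points and 100 by 25 points were recovered in 26 and 65 cases, none in the wrong direction, with 5 calls among the unchanged of the 159381 tiles. The changed tiles were drawn only from tiles in the middle range of methylation, so the recoveries do not describe highly methylated tiles. The test of HSPC to BFUE with no simulated change called 0. Adjusted p-values depend on how many tiles change, so these recoveries hold for few changed tiles and do not describe a comparison in which many tiles change.

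Whether equal replicate numbers marked matched libraries was checked on the deviations of log ratios from the stage means. Each neighbouring pair of stages within the progenitors and within the erythroblasts had correlations above 0.1 for all 3 numbers, from 0.121 to 0.164 between HSPC and BFUE and from 0.181 to 0.348 between LBaso and Poly. Same-numbered HSPC and CFUE libraries correlated by 0.0939 to 0.140. All 9 progenitor and all 15 erythroblast libraries lay closest to their own number within its own part of the series. Between progenitors and erythroblasts, same-numbered libraries correlated by -0.0438 to 0.0638. Pairing therefore came from the values, and it held for the steps within progenitors and within erythroblasts but not from CFUE to ProE or from HSPC to Ortho. Replicates were also compared with sampling noise. The median squared standardised difference of tiles between replicates of 1 stage was 1.29 to 2.89, against 0.455 for sampling alone. No technical duplicates were at hand to compare with, so this does not tell whether replicates came from separate DNA. For same-numbered Poly and Ortho libraries it was 1.43 to 1.49, and their mean squared difference of 3.48 to 3.73 was lower than the 9.20 to 11.7 between replicates within these stages. Other libraries of different stages were not compared in this way.

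Alternatives were a coverage minimum of 20, tiles with at least 5 CpGs, an upper coverage limit at the 99.9th percentile, the dispersion of the 2 stages alone, limma on log2 ratios and on median-centred percentages, a difference of 25 points, a replicate block and leaving out each library. For the overall level they were the mean over tiles, all methylated reads over all reads, and all CpGs of each library. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib, and in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8).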

Results

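Cytosine methylation was measured by enhanced reduced representation bisulfite sequencing, which reads bisulfite-converted DNA from the CpG-rich part of the genome, in human cells at 8 stages of red cell formation. The starting cells were CD34-positive stem and progenitor cells from umbilical cord blood (HSPC). The other stages were sorted from cultures of such cells. They were the erythroid progenitors BFUE and CFUE, which are burst-forming and colony-forming units, and 5 erythroblast stages: proerythroblasts (ProE), early and late basophilic erythroblasts (EBaso and LBaso), polychromatic erythroblasts (Poly) and orthochromatic erythroblasts (Ortho). Progenitors were separated by the IL-3 receptor, CD34 and CD36, and erythroblasts by glycophorin A, band 3 and alpha 4 integrin. Each stage had 3 libraries, 24 in all, and the series describes them as replicate sets of cells. No donor is given in the labels, so p-values measure the spread between these libraries. The median coverage of a listed cytosine was between 34 reads (EBaso replicate 3) and 83 reads. CpGs on the 22 autosomes covered by at least 10 reads in all 24 libraries numbered 1909139, and they gave 159381 tiles of 1000 bases with at least 3 such CpGs.

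The first question was how the overall level of methylation moved over erythroid differentiation. With each common CpG given equal weight, mean methylation was highest in BFUE and was lower in late erythroblasts. The mean over common CpGs was 44.9% ± 0.0526 (SD, n = 3) in HSPC, 45.8% ± 0.209 in BFUE, 45.1% ± 0.229 in CFUE and 44.8% ± 0.393 in ProE. It was 44.1% ± 0.619 in EBaso, 42.0% ± 0.538 in LBaso, 41.3% ± 0.805 in Poly and 41.2% ± 0.688 in Ortho. Highly methylated CpGs accounted for this difference in level. The share of CpGs over 80% methylated was 42.3% ± 0.173 (SD, n = 3) in HSPC and 31.9% ± 2.24 in Ortho, and the share between 20 and 80% was 7.99% ± 0.248 in HSPC and 18.7% ± 2.26 in Ortho. The share under 20% was 49.7% ± 0.0798 in HSPC and 49.4% ± 0.0234 in Ortho.

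**Figure D1:**
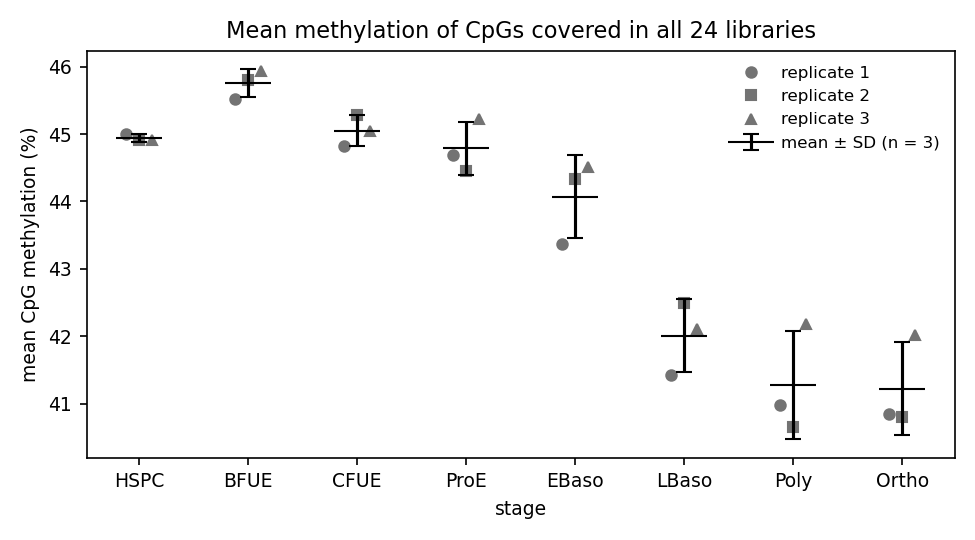
Mean methylation (percent, vertical axis, which does not start at 0) of the CpGs covered in all 24 libraries, by stage (horizontal axis); grey symbols are single libraries and black bars are the mean ± SD of 3 libraries. The stage means lie between 44.8% and 45.8% from HSPC to ProE and are 42.0% in LBaso, 41.3% in Poly and 41.2% in Ortho.

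Mean methylation was lower in Ortho than in HSPC, with a difference of -3.72 percentage points against a pooled SD of 0.488, and all 3 Ortho libraries lay below all 3 HSPC libraries. A two-sided exact permutation test of 3 libraries against 3 gave p = 0.1, the smallest p this design allows, and 0.2 after Benjamini-Hochberg adjustment over 10 stage comparisons. Over all 24 libraries the mean fell with the order of the stages (Spearman rho = -0.885, permutation p = 1e-05; Pearson r = -0.897, permutation p = 1e-05, the smallest value that the shuffles can give). Without the HSPC and Ortho libraries, those farthest from the middle of the order, r was -0.933 over 18 libraries. Within the 15 erythroblast libraries r was -0.898 (permutation p = 4e-05). Within the 9 progenitor libraries no steady trend was detected (r = 0.116, permutation p = 0.752), but the mean was higher in BFUE than in HSPC in all 3 same-numbered pairs (by 0.522 to 1.017 points) and lower in CFUE than in BFUE in all 3 (-0.883 to -0.522 points). Each of these steps had an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow. When each library was summarised by all methylated reads over all reads, so that deeply read CpGs weighed most, the difference between HSPC and Ortho was -1.66 points and the trend no longer passed the threshold (rho = -0.347, permutation p = 0.0973). By this measure BFUE was not above HSPC: replicates 1, 2 and 3 were at 37.5%, 35.99% and 36.96% in BFUE and at 37.9%, 36.04% and 37.6% in HSPC.

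**Figure D2:**
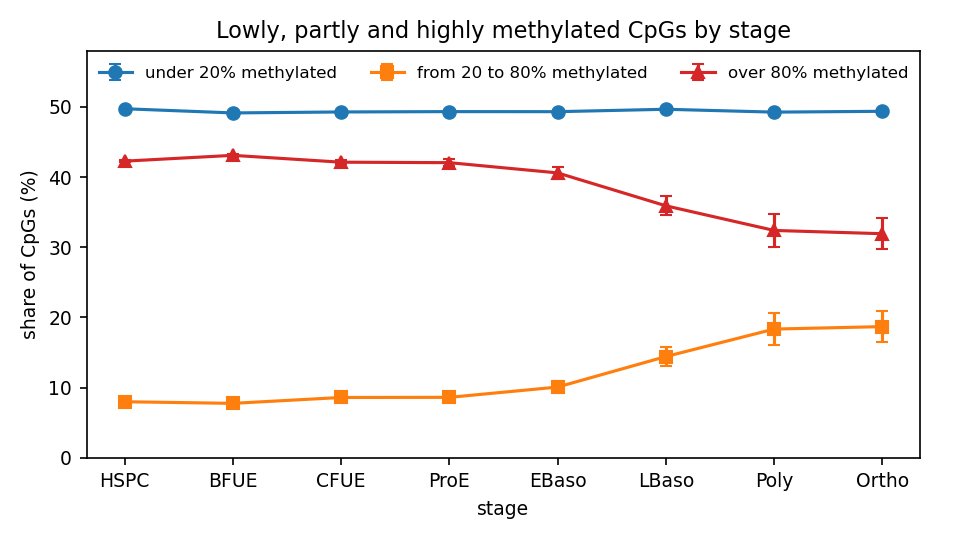
Share of common CpGs (percent, vertical axis) that were under 20%, from 20 to 80% and over 80% methylated at each stage (horizontal axis); symbols and bars are the mean ± SD of 3 libraries. The share over 80% is 42.3% in HSPC and 31.9% in Ortho, the share from 20 to 80% is 7.99% and 18.7%, and the share under 20% stays between 49.1% and 49.7%.

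The first step compared was HSPC against BFUE. HSPC were the starting cells and BFUE were sorted from culture, so any effect of culture is part of this comparison. BFUE had gained methylation at 1329 tiles and lost it at 10 (4 without HSPC replicate 3, 4 without BFUE replicate 1 and 19 without BFUE replicate 3). With libraries matched by replicate number, 28 tiles were lost in a fit of the progenitors and 21 in a fit of all stages, and 4 were lost with limma on log ratios. After median centring 715 tiles were higher and 7 lower in BFUE. The gained tiles had a mean of 45.4% ± 1.07 (SD, n = 3) in HSPC and 59.97% ± 0.431 in BFUE. Their level was 59.8% ± 1.19 in CFUE, 59.2% ± 1.71 in ProE, 55.1% ± 0.837 in LBaso, 58.8% ± 1.28 in Poly and 58.2% ± 0.737 in Ortho. A tile on chromosome 2, bases 43398001 to 43399000, rose from 11.3% ± 1.13 (SD, n = 3) in HSPC to 47.3% ± 3.50 in BFUE (limma-moderated quasi-binomial test, adjusted p = 7e-12), at 1683 to 2007 reads per library, and was at 66.4% in Ortho. Tiles on chromosome 7, bases 811001 to 812000, and chromosome 22, bases 18252001 to 18253000, rose by 35.3 and 35.2 points. The 3 named tiles that lost most differed by -29.7 to -17.2 points, and each of them was no longer called when single libraries were left out: without HSPC replicate 3, or without BFUE replicate 1, none of the 3 was called (differences of -27.6 to -13.4 points). The one on chromosome 7, bases 101546001 to 101547000, was also no longer called without HSPC replicate 1, HSPC replicate 2 or BFUE replicate 2 (-16.1, -17.4 and -16.3 points). Of the gained tiles, 752 had a mean over the 24 libraries between 20 and 80%, which was 2.96% of such tiles, and 416 were over 80% methylated. At a limit of 25 points in place of 10, 41 tiles were called.

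From BFUE to CFUE the direction turned. CFUE had lost methylation at 1001 tiles and gained it at 331. The lost tiles went from 78.5% ± 2.43 (SD, n = 3) in BFUE to 55.3% ± 1.53 in CFUE. They were at 56.4% ± 4.19 in ProE, 47.5% ± 1.68 in LBaso, 53.4% ± 1.66 in Poly and 53.6% ± 0.465 in Ortho. Several of these losses were nearly complete. On chromosome 19, bases 13058001 to 13059000, methylation fell from 88.7% ± 5.08 to 8.71% ± 5.88 (limma-moderated quasi-binomial test, adjusted p = 8.79e-08). On chromosome 7, bases 101799001 to 101800000, it fell from 89.1% ± 2.78 to 15.9% ± 1.94 (adjusted p = 1.42e-09) by the same test. On chromosome 17, bases 47326001 to 47327000, it fell from 84.8% ± 6.41 to 12.5% ± 1.83 and was at 0.614% in ProE. The 3 named gained tiles rose by 35.7 to 38.9 points, led by chromosome 6, bases 41975001 to 41976000, from 22.6% ± 11.3 to 61.5% ± 4.02. At a limit of 25 points 351 tiles were called, 321 of them lost. After median centring 370 tiles were higher and 579 lower in CFUE.

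Over both progenitor steps, from HSPC to CFUE, 1641 tiles gained and 899 tiles lost methylation. Any effect of culture is part of this comparison too, since CFUE were sorted from culture. Gained tiles went from 32.2% ± 0.354 (SD, n = 3) in HSPC through 43.4% ± 0.793 in BFUE to 49.7% ± 1.201 in CFUE. Lost tiles stood at 78.2% ± 0.737 in HSPC and 77.9% ± 2.57 in BFUE and at 54.2% ± 1.42 in CFUE. The tile with the largest gain, on chromosome 12, bases 132381001 to 132382000, rose from 13.2% ± 3.58 to 72.5% ± 1.63 (limma-moderated quasi-binomial test, adjusted p = 3.59e-10). It held 4 common CpGs of 20 listed. It was followed by tiles on chromosome 3, bases 129295001 to 129296000 (3.68% to 61.3%), chromosome 6, bases 41975001 to 41976000 (4.85% to 61.5%), chromosome 6, bases 159519001 to 159520000 (10.5% to 59.97%) and chromosome 5, bases 176858001 to 176859000 (4.75% to 53.8%). The tile with the largest loss, on chromosome 2, bases 159992001 to 159993000, fell from 85.9% ± 2.55 to 8.05% ± 2.71 (same test, adjusted p = 1.25e-10) and was at 0.0487% in Ortho. Tiles on chromosome 9, bases 119227001 to 119228000, chromosome 19, bases 13058001 to 13059000, chromosome 1, bases 211787001 to 211788000, and chromosome 7, bases 138037001 to 138038000, changed by -77.1, -76.6, -76.5 and -75.7 points. The losses were larger than the gains: among differences of at least 25 points the balance turned, with 202 tiles gained and 303 lost.

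The passage from the last progenitor to the first erythroblast stage, CFUE to ProE, involved few tiles. Methylation was higher in ProE at 25 tiles and lower at 42. On chromosome 1, bases 51086001 to 51087000, it was 85.1% ± 9.15 (SD, n = 3) in CFUE and 39.7% ± 7.96 in ProE (limma-moderated quasi-binomial test, adjusted p = 0.000268), and 6.97% in Ortho. On chromosome 22, bases 36651001 to 36652000, it was 79.9% ± 0.973 in CFUE and 44.9% ± 11.3 in ProE. A tile on chromosome 18, bases 31400001 to 31401000, held 20.2%, 21.997% and 20.8% in HSPC, BFUE and CFUE and 77.5% in ProE, and lay between 69.7% and 78.3% in the later stages. Equal replicate numbers did not mark matched libraries between progenitors and erythroblasts, so any difference between the cells used for progenitors and for erythroblasts is part of this comparison. A further gained tile (chromosome 10, bases 5101001 to 5102000) rose by 25.6 points. The tiles on chromosome 17, bases 73752001 to 73753000 (24.3 points), and chromosome 22, bases 30680001 to 30681000 (-31.8 points), were no longer called without ProE replicate 1 (23.8 and -31.1 points), the former also without CFUE replicate 1 or CFUE replicate 2 (22.7 and 23.9 points). With the dispersion taken from the 2 stages alone 2 tiles were called, none of them a named one, and the count was 34 without CFUE replicate 1 (9 higher, 25 lower), 42 without CFUE replicate 2 (20 and 22), 32 without ProE replicate 1 (12 and 20) and 35 without ProE replicate 2 (13 and 22). Without CFUE replicate 3 the count of tiles higher in ProE was 15.

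**Figure D3:**
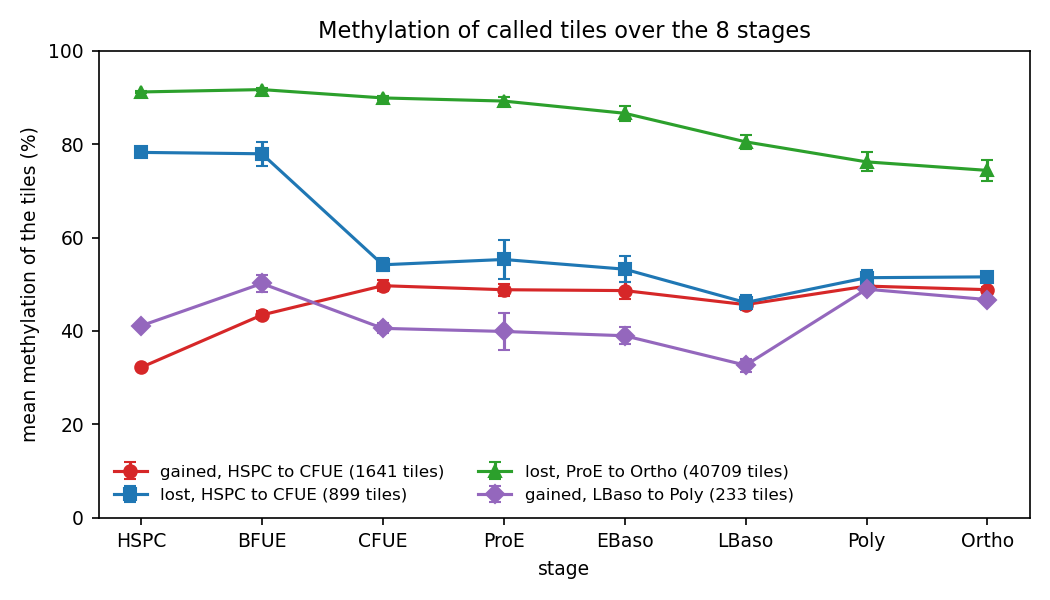
Mean methylation (percent, vertical axis) at each stage (horizontal axis) of 4 sets of called tiles; symbols and bars are the mean ± SD of 3 libraries. Tiles lost from HSPC to CFUE go from 78.2% to 54.2%, tiles gained in the same interval from 32.2% to 49.7%, tiles lost from ProE to Ortho from 89.2% to 74.4%, and tiles gained from LBaso to Poly from 32.7% to 48.96%; each set was chosen on the stages in its name.

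Terminal differentiation, from ProE to Ortho, brought a loss of methylation over much of the measured genome. Of the 159381 tiles, 40709 lost methylation and 70 gained it (190 gained without ProE replicate 3 and 109 without Ortho replicate 3). The lost tiles went from 89.2% ± 0.803 (SD, n = 3) in ProE through 86.6% ± 1.63 in EBaso, 80.5% ± 1.496 in LBaso and 76.2% ± 2.03 in Poly to 74.4% ± 2.32 in Ortho. Their median fall was modest: the median change of a lost tile was -13.95 points, and 767 tiles of either direction differed by 25 points or more. Tiles with a mean under 20% over all libraries were at 2.93% ± 0.124 in ProE and 2.94% ± 0.173 in Ortho, with 4 gained and 4 lost among 34408. Among tiles over 80% methylated, 34.2% were lost.

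The named tiles lost from ProE to Ortho were led by chromosome 14, bases 67877001 to 67878000, which fell from 75.4% ± 16.3 (SD, n = 3) to 30.8% ± 11.2 (limma-moderated quasi-binomial test, adjusted p = 6.4e-05) at 33 to 381 reads per library. Next came chromosome 3, bases 27325001 to 27326000, from 82.1% ± 3.52 to 41.3% ± 2.54, and chromosome 22, bases 30680001 to 30681000, from 49.9% ± 9.65 to 11.6% ± 3.78. Tiles on chromosome 5, bases 152439001 to 152440000, and chromosome 6, bases 141581001 to 141582000, changed by -36.6 and -36.1 points. The largest gain, on chromosome 18, bases 9223001 to 9224000, was from 43.8% ± 17.9 to 72.7% ± 7.65 (same test, adjusted p = 0.00373), in a tile at 87.9% in HSPC and 46.7% in CFUE. The other gained tiles named were on chromosome 12, bases 124247001 to 124248000, and chromosome 2, bases 10447001 to 10448000, which rose by 18.4 and 20.2 points, and on chromosome 1, bases 161474001 to 161475000, and chromosome 2, bases 25022001 to 25023000. These last tiles differed by 22.6 and 21.004 points, and without ProE replicate 1 they were no longer called (18.1 and 15.2 points). Subtracting each library's median over tiles turned the direction, with 56839 tiles higher and 2379 lower. The tile median was 90.1% in ProE and 78.3% in Ortho, while the median change of a tile was -4.59 points. Centring therefore raised tiles that fell by less than the library medians did.

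The number of called tiles differed between the erythroblast steps, but whether the loss itself was uneven was not tested. From EBaso to LBaso 2470 tiles lost methylation and none gained it, from a mean of 86.3% ± 1.94 (SD, n = 3) to 74.1% ± 1.31. The named tiles were chromosome 2, bases 2945001 to 2946000, chromosome 19, bases 15610001 to 15611000, and chromosome 5, bases 31782001 to 31783000, which changed by -24.8, -23.3 and -21.7 points. Matching libraries by replicate number raised the count to 3947, of which 3945 were lost. The count was 0 with the dispersion of the 2 stages alone, 140 with limma on log ratios and 370 after median centring (180 higher, 190 lower). It rested on single libraries: it was 0 without EBaso replicate 2, 444 without LBaso replicate 1, 1183 without EBaso replicate 3, 4551 without EBaso replicate 1 and 4506 without LBaso replicate 2, and the chromosome 2, 19 and 5 tiles were not called without EBaso replicate 2 (-28.0, -21.6 and -24.4 points). The chromosome 2 tile was also not called without LBaso replicate 1, LBaso replicate 3 or EBaso replicate 1 (-27.5, -24.4 and -24.6 points), and the chromosome 5 tile without LBaso replicate 1, LBaso replicate 3 or EBaso replicate 3 (-20.8, -19.7 and -14.2 points).

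From ProE to EBaso no tile was called, although 10986 tiles had an unadjusted p under 0.05 in the limma-moderated quasi-binomial test, 10555 of them lower in EBaso. The count was also 0 with limma on log ratios and with libraries matched by replicate number. Mean methylation was lower in EBaso than in ProE in all 3 same-numbered pairs, with a mean difference of -0.715 points (-1.326 to -0.113). The two-sided exact permutation p was 0.2 without pairing (n = 3 per stage) and 0.25 when signs were flipped within pairs, the smallest p that 3 pairs can give. Between Poly and Ortho no tile was called either: 10433 had an unadjusted p under 0.05 (5857 higher and 4576 lower in Ortho), limma on log ratios called 0 and limma on median-centred percentages called 56 (17 higher, 39 lower). The count was 3 without Ortho replicate 3. The means over common CpGs were 41.3% ± 0.805 in Poly and 41.2% ± 0.688 in Ortho (SD, n = 3). The share of CpGs under 20% was higher in Ortho in all 3 same-numbered pairs, by 0.0712 to 0.169 points (49.26% ± 0.0261 in Poly and 49.37% ± 0.0234 in Ortho; exact permutation p = 0.1, the smallest possible, and 0.167 adjusted).

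Between LBaso and Poly both directions occurred, with 233 tiles gained and 270 lost. The gained tiles were partly methylated: their mean was 32.7% ± 1.42 (SD, n = 3) in LBaso and 48.96% ± 0.695 in Poly, after 41.1% in HSPC, 50.2% in BFUE, 40.6% in CFUE and 39.9% in ProE. The lost tiles were highly methylated, with 82.5% ± 1.45 in LBaso and 69.8% ± 1.31 in Poly. A level lower in LBaso than in both neighbours was not limited to the gained tiles. Tiles gained from HSPC to CFUE were at 48.7% ± 1.87 in EBaso, 45.6% ± 0.826 in LBaso and 49.6% ± 0.921 in Poly. Tiles with a mean under 20% were at 2.93% ± 0.110, 2.61% ± 0.0850 and 3.03% ± 0.128. Tiles with a mean over 80% fell at both steps (91.3%, 87.3% and 85.0%). The cause was not tested. The named gained tiles were at a high level in HSPC, lower from CFUE to LBaso, and higher again in Poly. On chromosome 17, bases 3835001 to 3836000, methylation was 81.2% in HSPC, 33.4% in CFUE, 26.7% ± 2.84 in LBaso and 71.1% ± 6.96 in Poly (limma-moderated quasi-binomial test, adjusted p = 0.00329). On chromosome 16, bases 85551001 to 85552000, a tile with 18 CpGs read 3428 to 5738 times, it was 89.5% in HSPC, 53.5% in CFUE, 45.8% ± 6.67 in LBaso and 80.9% ± 0.940 in Poly (same test, adjusted p = 2.58e-05). With the dispersion of the 2 stages alone the tile on chromosome 16 was still called, and the tile on chromosome 17 and the other 4 named tiles of this step were not (adjusted p from 0.057 to 0.388, limma moderation). A further gained tile on chromosome 21, bases 34622001 to 34623000, was not called without LBaso replicate 1, LBaso replicate 3, Poly replicate 1 or Poly replicate 2 (25.2 to 35.8 points). The 3 named lost tiles differed by -20.6 to -27.7 points, and none of them was called without LBaso replicate 2 or without Poly replicate 2 (-18.6 to -27.3 points). The lost tile on chromosome 18, bases 38704001 to 38705000, was also not called without LBaso replicate 3 (-25.9 points), and that on chromosome 2, bases 1373001 to 1374000, without LBaso replicate 3 or Poly replicate 1 (-22.7 and -23.0 points). The remaining lost tile was on chromosome 3, bases 14748001 to 14749000.

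The balance of the LBaso to Poly calls depended on single libraries and on the test. It was 194 gained and 611 lost without LBaso replicate 1, 169 and 28 without LBaso replicate 2, 149 and 88 without LBaso replicate 3, 157 and 113 without Poly replicate 1, 170 and 86 without Poly replicate 2, and 219 and 1153 without Poly replicate 3. Matching libraries by replicate number gave 500 gained and 652 lost, limma on log ratios gave 35 and 0, and median centring gave 1132 and 185.

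Over the whole series, from HSPC to Ortho, 48835 tiles lost and 2415 tiles gained methylation, which together made 32.2% of the tiles. The lost tiles had a mean of 91.3% ± 0.234 (SD, n = 3) in HSPC and 74.7% ± 2.22 in Ortho, and the gained tiles 32.2% ± 0.358 and 49.8% ± 0.327. The named losses were nearly complete. On chromosome 18, bases 48533001 to 48534000, methylation was 91.5% ± 4.02 in HSPC, 94.1% in BFUE, 36.5% in CFUE, 13.7% in ProE and 2.04% ± 1.82 in Ortho (limma-moderated quasi-binomial test, adjusted p = 2.64e-10), at 65 to 283 reads per library. On chromosome 1, bases 206832001 to 206833000, it fell from 91.9% ± 2.84 to 4.39% ± 1.65, and on chromosome 9, bases 135874001 to 135875000, a tile with 7 CpGs, from 91.1% ± 3.48 to 4.33% ± 0.970. Tiles on chromosome 12, bases 124975001 to 124976000, and chromosome 20, bases 23114001 to 23115000, changed by -86.6 and -86.3 points. The largest gain was in the tile on chromosome 12, bases 132381001 to 132382000, from 13.2% ± 3.58 to 80.9% ± 0.638 (same test, adjusted p = 1.55e-11). This tile held 4 common CpGs of 20 listed. The tiles on chromosome 5 (bases 176858001 to 176859000), chromosome 6 (bases 41975001 to 41976000), chromosome 9 (bases 100281001 to 100282000) and chromosome 2 (bases 43398001 to 43399000) rose by 62.4, 59.97, 56.0 and 55.1 points.

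Tiles that fell by 50 points or more from HSPC to Ortho numbered 111. Their mean was 85.0% ± 1.22 (SD, n = 3) in HSPC, 83.7% ± 4.27 in BFUE, 38.6% ± 1.19 in CFUE, 29.5% ± 5.35 in ProE and 18.8% ± 0.678 in Ortho. Equal replicate numbers did not mark matched HSPC and Ortho libraries, so any difference between the cells used for progenitors and for erythroblasts is part of these counts, of the difference in mean methylation and of the trend over all stages. Any effect of culture is part of them too, since HSPC were the starting cells and the other stages came from culture. Median centring turned the direction here too, with 67956 tiles higher and 5336 lower. In the test across all 8 stages together 65715 tiles, 41.2% of those tested, differed by at least 10 points between some pair of stages.

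**Figure D4:**
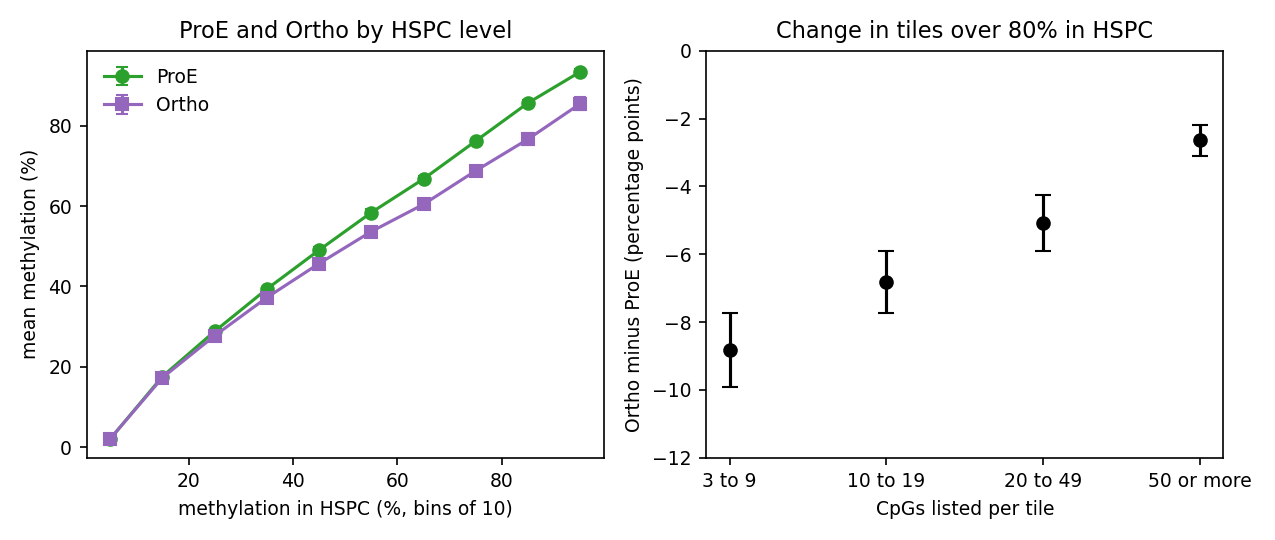
Left, mean methylation (percent, vertical axis) in ProE and Ortho of tiles binned by their HSPC level (percent, horizontal axis); right, the Ortho minus ProE difference (percentage points, vertical axis) of tiles over 80% methylated in HSPC, by the number of CpGs listed in the tile (horizontal axis); symbols and bars are the mean ± SD of 3 libraries on the left and of 3 same-numbered pairs on the right. Ortho lies below ProE in all bins from 20% upward, and the difference is -8.82 points in tiles with 3 to 9 CpGs and -2.64 points in tiles with 50 or more.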

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

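The mitochondrial share without single libraries was chosen after the share had been seen; the other tests here were set before their results. Mitochondrial cytosines were outside the mean levels and tiles compared between stages. Their apparent methylation had a median of 0.101% over the libraries and was highest in Ortho replicate 2, at 0.296% (72 of 24294 reads; exact Clopper-Pearson 95% interval 0.232 to 0.373%), where a count of 0 would allow 0.0123% from 3 reads. The next highest library was at 0.187%. The reads given here are coverage counts, in which a read counts once for each cytosine it covers, and the interval covers counting error only.

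Mitochondrial coverage was summed over 44 cytosines listed in all 24 libraries and taken as a percent of the coverage summed over the common autosomal CpGs. This share counts a read once for each cytosine it covers and is not a share of all reads. It was 5.57-fold higher in HSPC than in Ortho. The size of this difference depended on Ortho replicate 1: it was 8.44-fold without that library and 4.57-fold to 6.63-fold without any other HSPC or Ortho library. The share was 0.0946% ± 0.0313 (SD, n = 3) in HSPC, 0.210% ± 0.0475 in CFUE, 0.107% ± 0.0503 in ProE, 0.0232% ± 0.0102 in Poly and 0.0170% ± 0.0102 in Ortho, and an exact permutation test of HSPC against Ortho gave p = 0.1, the smallest this design allows. The coverage minimum of the listing is argued against, since the 5.57-fold difference is on cytosines listed in every library. A few very deep cytosines are argued against too, since the difference was 5.77-fold without the 5 deepest. No biological explanation was tested. A lower mitochondrial DNA content in late erythroblasts and a shift of library composition between mitochondrial and nuclear fragments both stay open.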

How the results depend on the processing

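Of 188 recomputed summary values for 13 results, 132 stayed within set bounds. The HSPC to Ortho difference in mean methylation had to keep its direction and move by less than the pooled SD of 0.488 points. The trend had to keep its direction and its side of the threshold. Counts of tiles had to stay within 1.5 times the reported count, without a turn in the balance of gained and lost tiles. In 14 of the others the balance of gained and lost tiles turned. Some of the 132 could not differ: the replicate block and leaving out EBaso replicate 3 do not enter the HSPC to Ortho difference in mean methylation. The upper coverage limit and the coverage minimum of 20 moved no summary value past these bounds. The replicate block within progenitors or erythroblasts, the thinning to equal reads and leaving out EBaso replicate 3 were chosen after seeing the data. Causes were not tested unless given. The planned promoter and gene list alternatives were not run, for want of an hg19 annotation here.

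The difference in mean methylation from HSPC to Ortho was -6.42 points over tiles, -4.95 over all CpGs of each library and -1.66 over all reads, where the trend was no longer past its threshold (rho = -0.347). Leaving out replicate 1, 2 or 3 gave -4.13 to -3.50 points and rho from -0.935 to -0.858. At 25 points, which calls fewer tiles by construction, counts were 41 (HSPC to BFUE), 351 (BFUE to CFUE), 9 (CFUE to ProE), 0 (EBaso to LBaso), 20 (LBaso to Poly, 19 gained), 505 (HSPC to CFUE, 303 lost), 767 (ProE to Ortho), 4135 (HSPC to Ortho) and 5992 (any stage). With at least 5 CpGs, which leaves 96857 tiles, they were 892, 720, 36, 533, 250 (174 gained), 1516, 16631, 22422 and 29551 in the same order. Dispersion from the 2 stages alone gave 2 for CFUE to ProE, 0 for EBaso to LBaso and 62 for LBaso to Poly, all gained. Limma on log ratios gave 33, 140 and 35 for these steps, the last all gained. Median centring gave 722 for HSPC to BFUE, 370 for EBaso to LBaso (190 lost, against 2470 of 2470), 1317 for LBaso to Poly (1132 gained, against 233 of 503), 56 for Poly to Ortho, 59218 for ProE to Ortho and 73292 for HSPC to Ortho; the last 2 turned to gains because the library medians fell. Thinned to equal reads, CFUE to ProE gave 41 and LBaso to Poly 199 (136 gained).

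With 1 replicate block over all stages, CFUE to ProE gave 343 (186 gained), where the numbers did not pair the libraries, and LBaso to Poly 972. The block within progenitors or erythroblasts gave 3947 for EBaso to LBaso and 1152 for LBaso to Poly, and changed the total of no other comparison by over 1.5 times, although the tiles lost from HSPC to BFUE went from 10 to 28.

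Leaving out single libraries gave 1023 to 1295 tiles for HSPC to BFUE, 932 to 1240 for BFUE to CFUE, 32 to 86 for CFUE to ProE, 0 to 4551 for EBaso to LBaso, 197 to 1372 for LBaso to Poly, 0 to 3 for Poly to Ortho, 2126 to 2327 for HSPC to CFUE, 36338 to 46934 for ProE to Ortho and 47671 to 56091 for HSPC to Ortho. For any stage, leaving out all 8 libraries of replicate 1, 2 or 3 gave 58184 to 68635, and leaving out EBaso replicate 3 gave 65740. The 57 named tiles, a tile being counted once for each comparison that named it, gave 737 recomputed differences, and 74 were no longer called. That 0 changed sign says little. The rule for naming tiles asked for separated libraries, so leaving out 1 library could not turn the sign. Several other settings changed the test or the limit and kept the same difference. Median coverage was lowest in EBaso replicate 3, at 34; without that library ProE to EBaso stayed at 0 and EBaso to LBaso gave 1183. After thinning to equal reads, 86.9% of the tiles lost from ProE to Ortho and 67.9% of those gained from HSPC to BFUE were still called.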

Other observations

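The loss of methylation from ProE to Ortho differed between chromosomes. Mean tile methylation on chromosome 19 changed least (-3.70 ± 0.358 points, SD over n = 3 same-numbered pairs), with 12.7% of tiles lost, and on chromosome 18 most (-7.35 ± 0.728 points), with 32.4% lost. The highest share of lost tiles was on chromosome 8 (33.7%). These values are over all tiles of a chromosome and were not adjusted for CpG number or starting level. A different mix of tiles can therefore be part of the difference between chromosomes. Tiles gained from HSPC to Ortho lay together in places: 16 of the 72 tested tiles on chromosome 9, bases 139500001 to 139600000, were gained, where the highest window in 100 shuffles held 7. That window also held 9 tiles gained from HSPC to BFUE, against 5 in shuffles. Of the tiles lost by 50 points or more, 4 lay on chromosome 16, bases 88500001 to 88600000, against 2 in shuffles. These windows were chosen after their values were seen.

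Calls from comparisons of different libraries overlapped. The dispersion of each tile came from all 24 libraries and favours the same tiles in each list, so the expectation for independent lists is a guide and not the value without any relation. Of the 233 tiles gained from LBaso to Poly, 92 had been lost from BFUE to CFUE, where independent lists would share 1.46, and among partly methylated tiles the overlap was 80 of 170 against 5.01. Of the same 233, 100 had been gained from HSPC to BFUE, against 1.94. Tiles gained from HSPC to CFUE were seldom among those lost from ProE to Ortho, with 63 shared against 419 for independent lists.

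The following tests were chosen after the result was seen: the level of unmethylated tiles, thinning to equal reads and over-conversion for the ProE to Ortho loss, and the return of lost tiles for the LBaso to Poly gains. The other tests below were set before their results.

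For the lower methylation from ProE to Ortho, bases left unconverted in ProE and over-conversion in Ortho are argued against. Unequal depth could be tested only in part. If bases left unconverted in ProE made the difference, tiles under 10% in HSPC would stand in ProE at least as high as the fall in the mean; they were at 2.04% ± 0.0786 (SD, n = 3), under the smallest fall among same-numbered pairs (-3.20 points). After every library was thinned to the same reads per tile, 86.9% of the lost tiles were still called, so unequal read numbers did not make most of these calls. Thinning keeps the expected percent of each library in a tile. It therefore cannot tell whether the levels themselves were biased by depth. Over-conversion of methylated bases in Ortho would remove the same share from all highly methylated tiles; among tiles over 80% in HSPC, those with 3 to 9 CpGs lost 9.56% ± 1.25 (SD, n = 3 pairs) of their ProE level and those with 50 or more lost 2.84% ± 0.507, a difference of 6.73 ± 0.746, which argues against it as the whole cause. A change that comes with the stage stays open.

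For the tiles gained from LBaso to Poly, cells with HSPC-like methylation mixed into Poly are argued against: they would raise every tile that is high in HSPC, and 17 tiles lost from HSPC to CFUE and under 5% in ProE changed by a median of 0.0706 points, although their HSPC median was 58.1%. Shifted read weights among CpGs are argued against too, since the median gain with equal weights was 0.971 of that from summed reads. A return of tiles that had lost methylation cannot be told apart from other courses. From HSPC to CFUE, libraries that entered the choice of the set only through the dispersion, 32.6% of its tiles fell by 10 points or more, under the 50% set as a bound, and 43.3% rose by as much, against 3.85% and 6.45% of all tiles with a mean of 20 to 80%.

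How the ProE to Ortho loss was distributed was tested with 3 hypotheses. Among tiles over 80% methylated in HSPC, the fall was larger in tiles with 3 to 9 CpGs than in tiles with 20 or more (-3.83 ± 0.301 points, SD, n = 3 pairs), which is consistent with a dependence on CpG number. The loss was also grouped along chromosomes. The SD of mean differences between 1326 bins of 1 megabase was 3.14 points, above the highest of 1000 shuffles within classes of CpG number (1.04), and bin values correlated between replicate numbers by 0.954 to 0.961 across bins, which are not independent replicates. The bin on chromosome 19, bases 31000001 to 32000000, was at -16.4 ± 1.16 points (60 tiles) and the bin on chromosome 15, bases 91000001 to 92000000, at -0.934 ± 0.333 (64 tiles). Whether the loss was proportional to the starting level cannot be told apart from an unequal one: the Ortho to ProE ratio spanned 0.0675 over bins from 20 to 100%, and 0.0235 to 0.0977 in single replicate numbers.

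Other splits of the same libraries were tested for each count. With 10 splits of 6 libraries a share under 0.05 cannot be reached, and only the counts are given. The real split gave 1339 tiles from HSPC to BFUE, 1332 from BFUE to CFUE, 67 from CFUE to ProE, 2540 from HSPC to CFUE and 51250 from HSPC to Ortho, against a highest other split of 0 in each. It gave 2470 from EBaso to LBaso against 11, 503 from LBaso to Poly against 335 and 40779 from ProE to Ortho against 164; in each of these 1 of 10 splits was as large, the real one. In the splits that also parted all same-numbered libraries the highest other was 0. From ProE to EBaso and from Poly to Ortho the real count was 0, reached by all 10 splits, with highest others of 0 and 7. For all 8 stages, 1 of 100 splits, the real one, reached 65715 tiles, the smallest share these splits can give, and the highest other was 37164. This argues against a random grouping of the 24 libraries. The shuffles did not keep the matched replicate numbers, and some of them still called many tiles.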
